A study of Mus musculus with 3 samples.

How the data were processed

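Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed in 3 libraries from C57BL/6 mouse CD4+ T cells, with 1 library for each antibody: Stat3, acetylated histone H3 (H3Ac) and histone H3 trimethylated at lysine 4 (H3K4me3). The Stat3 antibody is called phospho-Stat3 in one label and Stat3 in the others. Per the labels' protocols, cross-linked chromatin was digested with micrococcal nuclease to about 80% mononucleosomes and 20% dinucleosomes, each precipitation gave about 100 ng of DNA, and the DNA was sequenced on an Illumina 1G instrument. No input or control antibody library was used here, so enrichment was measured against the genome or the surroundings within each library.

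The deposited files list aligned reads of 25 bases, with chromosome, start, end, a match string that shows mismatched bases, and strand. Their build is mm9, per the submitters' processing notes. The aligner and its settings are not given in the sources used here. On all 20 chromosomes used (1 to 19 and X), the last read ended inside the mm9 length, taken from the mm9 table of the R package GenomeInfoDb 1.38.1.

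Reads were counted at most 1 time per position and strand, and each was moved 75 bp towards its 3′ end. This left 2645166 Stat3, 4058220 H3Ac and 3160348 H3K4me3 reads on the chromosomes used. The genome was divided into windows of 200 bp, and a window was called at an upper-tail Poisson p of 1e-06 or less. For Stat3 the background was the larger of the genome mean and the mean of 51 windows centred on the tested window (about 10 kb), and called windows up to 200 bp apart were merged. For both marks the background was the genome mean, and windows up to 600 bp apart were merged. Density is given as RPKM, reads per kb scaled to the number of reads used in the library.

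The caller was tested on simulated libraries of the same depth. Without signal it called 1 Stat3, 12 H3Ac and 3 H3K4me3 regions over 13194974 windows. The simulated background was Poisson, with the genome mean for both marks and the local mean for Stat3, as the caller assumes. Few calls therefore followed from the threshold, and false calls in the real reads were not measured. Of 50 planted Stat3 windows with a mean of 5 added reads, 40% were recovered, and with 10 added reads 90%. At 20 added reads all 50 were recovered.

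Regions overlapped when they shared at least 1 bp. Observed overlap was set beside 100 random placements of the Stat3 regions on their own chromosomes, and beside 100 placements restricted to windows that held a Stat3 read. Shares have Wilson 95% intervals, counts have exact Poisson intervals, and ratios of counts have exact intervals conditional on their sum. All intervals cover counting error only, because reads without molecular identifiers are not independent molecules. With 1 library per antibody there was no replicate check, no test between conditions, and no p-value over regions.

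The regions named individually were the 15 with the highest Stat3 density, by a rule fixed before the data were examined that leaves out satellites and regions with reads on a single strand. Satellites were identified by a stand-in defined after the data were seen. A region was left out when its share of mismatched reads, pooled over the 3 libraries, exceeded the expected share (binomial test, Benjamini-Hochberg adjusted p of 0.01 or less). Regions with at least 90% of reads on either strand were also left out. This removed 47 mismatch-rich and 23 strand-biased regions, 67 in all, and 1580 regions remained. Overlaps, regions per Mb by mark class and the X chromosome comparison use every called region; strength classes, read profiles, clusters, classes of mark width and strand offsets at Stat3 regions use the remaining 1580.

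The strand offset was estimated from the distances between plus-strand and minus-strand 5′ ends. Pair counts were smoothed over 15 bp, the most frequent distance was found between 60 and 250 bp, and the offset is the vertex of a quadratic fitted within 25 bp of it, with an error from leaving out each chromosome in turn. The vertex and the most frequent distance differ where the peak is asymmetric.

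Genes were not assigned to regions, because the gene table used here is on GRCm38 and coordinates were not converted between builds. Planned results that need genes, promoters or genome sequence on mm9 were therefore not run: distance to transcription start sites, genes carrying each mark, promoter correlations, gene lists, helper T cell loci and the STAT motif. Correlations across 2 kb bins were computed in place of the promoter correlations. The alternatives tried were all reads kept, window thresholds of 1e-04 and 1e-09, libraries thinned to equal reads, reads not moved, the genome mean as the Stat3 background, and a larger minimum overlap. Alternatives added after seeing the data were a 1 kb margin around mark regions, removal of mismatch-rich regions, and other bins for the correlations. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.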

Results

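Stat3 binding, H3Ac and H3K4me3 were mapped in mouse CD4+ T cells polarized with IL-6 and IL-23. Stat3 is the transcription factor activated downstream of both cytokines, H3K4me3 marks mainly active promoters, and H3 acetylation marks active promoters and enhancers. Cells were activated with irradiated antigen-presenting cells and T cell receptor stimulation, polarized for 3 days, and stimulated again for 2 h through CD3 and CD28 in the presence of IL-23. The series holds 1 library per antibody, with 2703760 Stat3, 4269017 H3Ac and 4347196 H3K4me3 reads. Reads repeating a position and strand made up 2.05% of the Stat3 library, 4.91% of the H3Ac library and 27.3% of the H3K4me3 library.

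The 3 antibodies gave very different landscapes. H3K4me3 was concentrated in 21323 regions that covered 0.996% of the genome and held 79.2% of its reads. The H3Ac library was less concentrated in called regions, with 24192 regions holding 28.2% of its reads. With 1 library each, a difference between marks and one between precipitations cannot be told apart. Stat3 gave 1647 narrow regions, with a median width of 200 bp, that held 1.01% of its reads. Median widths were 1000 bp for H3K4me3 and 600 bp for H3Ac, and the widest regions reached 40.4 kb and 60.2 kb. The number of Stat3 regions depended strongly on the calling rule. It was 4144 at a window threshold of 1e-04, 771 at 1e-09, and 5421 with the genome mean as the only background. H3Ac regions also fell below H3K4me3 regions in number at 1e-09, with 15531 against 18776. With libraries thinned to equal reads the counts were 16825 and 19860.

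Among the 1580 regions that passed the mismatch and strand filters, the strongest Stat3 region lay on chromosome 11 at 100801001 to 100801200 (mm9). It held 97 reads, a density of 183 RPKM (reads per kb scaled to library size; 95% interval 149 to 224), and was 113 times as dense as the surrounding 10 kb. It overlapped no mark region, although H3K4me3 density over the 2 kb around it was 32.3 and H3Ac density was 7.89, against a genome mean of 0.379 for each. The next strongest were on chromosome 16 at 19960801 to 19961000, with a density of 115 (88.2 to 148), and chromosome 6 at 51962601 to 51962800, with 111.5 (84.9 to 144). Their intervals overlapped, so their order was not resolved at this depth.

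The 15 strongest of the 1580 Stat3 regions that passed the filters differed in their chromatin setting. Both marks overlapped 6 of them, including chromosome 6 at 51962601 to 51962800 and chromosome 10 at 79538001 to 79538400, where H3K4me3 density over 2 kb was 38.0 and 41.0. H3Ac alone overlapped 3, among them chromosome 10 at 82258201 to 82258400, where H3Ac density was 6.16 and H3K4me3 density 3.01. Chromosome 7 at 20402801 to 20403000, in the same class, had more H3K4me3 nearby, with densities over 2 kb of 20.7 for H3Ac and 19.1 for H3K4me3. The other 6 overlapped neither mark. Chromosome 1 at 157494801 to 157495000 had 42 Stat3 reads in the region but only 12 H3Ac and 4 H3K4me3 reads over 2 kb. Chromosome 1 at 80012201 to 80012400 had 49 Stat3 reads with 18 H3Ac and 4 H3K4me3 reads over 2 kb. Densities were computed from these 3 libraries without an input library.

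**Figure D1:**
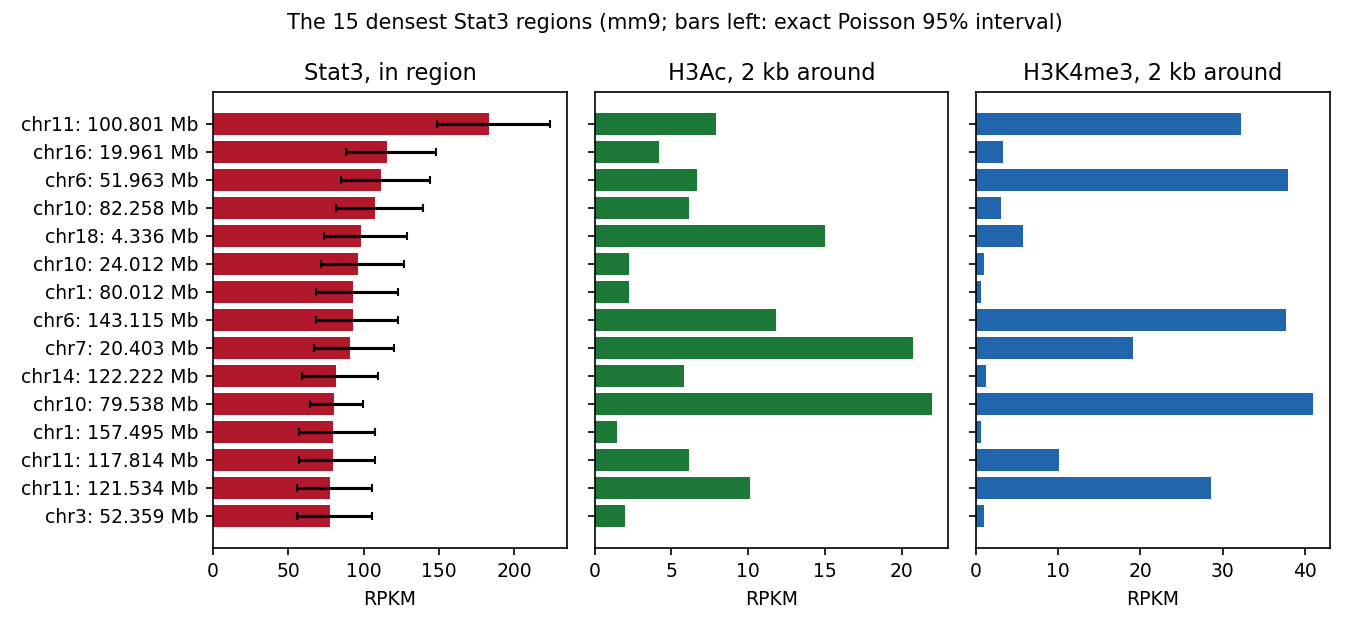
The 15 densest of the 1580 Stat3 regions that passed the mismatch and strand filters, named by chromosome and start on mm9, with Stat3 density in the region (left, with exact Poisson 95% intervals) and density over the surrounding 2 kb in the H3Ac (middle) and H3K4me3 (right) libraries, in RPKM. The strongest of these has a Stat3 density of 183, and mark densities differ widely among regions of similar Stat3 density. Some mismatch-rich regions, not shown, were denser.

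A question set by the design was whether Stat3 regions coincide with these marks. H3Ac regions overlapped 658 of 1647 Stat3 regions, or 39.95% (95% interval 37.6 to 42.3), and H3K4me3 regions overlapped 500, or 30.4% (28.2 to 32.6). Random placement gave means of 0.944% for H3Ac and 1.07% for H3K4me3. Placement on windows with a Stat3 read gave 3.48% and 3.69%, and the highest of 100 such placements were 4.68% and 4.86%. Both marks overlapped 24.5% of Stat3 regions, H3Ac alone 15.4%, H3K4me3 alone 5.83%, and neither mark 54.2% (51.8 to 56.6).

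The higher overlap with H3Ac than with H3K4me3 depended on depth and threshold. With libraries thinned to equal reads before repeats were removed, overlap was 26.1% (24.0 to 28.3) for H3Ac and 27.2% (25.1 to 29.4) for H3K4me3. At a window threshold of 1e-09 it was 25.03% (22.1 to 28.2) and 26.7% (23.7 to 30.0). The intervals overlapped in both settings, so the order of the marks was not resolved there. Overlapping regions included, 60.3% of Stat3 regions were within 1 kb of an H3Ac region, 44.0% were within 1 kb of an H3K4me3 region, and 35.9% had neither within 1 kb; this margin was not set beside random placements.

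**Figure D2:**
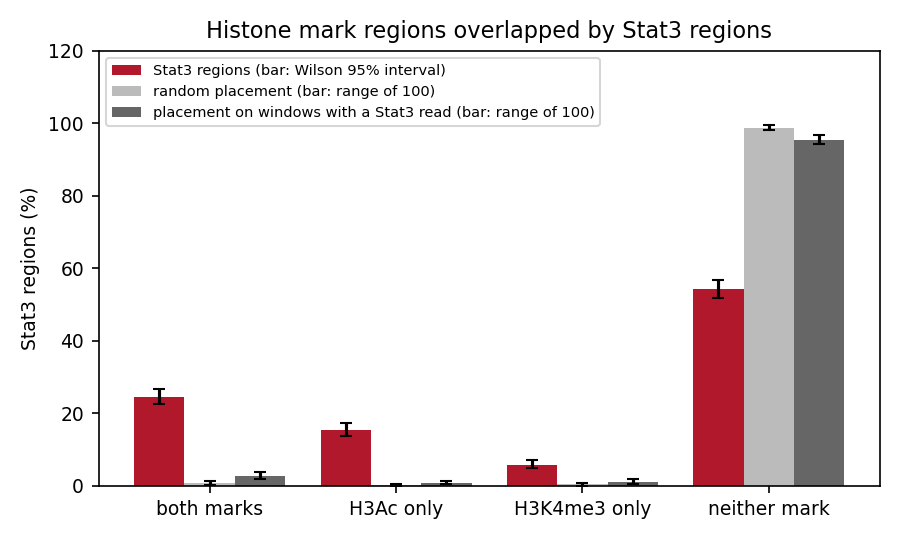
Share of the 1647 Stat3 regions (percent) that overlapped regions of both marks, H3Ac only, H3K4me3 only or neither (red, Wilson 95% intervals), beside 100 random placements (light grey) and 100 placements on windows with a Stat3 read (dark grey), each as the mean with its range. Neither mark overlapped 54.2% of Stat3 regions, against a mean of 98.7% under random placement.

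Per unit of marked sequence, Stat3 regions were densest where an H3Ac region but no H3K4me3 region was called. H3K4me3 was not absent there: its density was 2.97 RPKM, against 0.0736 with neither mark called and 37.4 with both. H3Ac density was likewise 2.94 RPKM with H3K4me3 only, against 0.265 with neither. There were 47.2 Stat3 regions per Mb (41.5 to 53.4) in sequence with H3Ac only, 23.3 (21.1 to 25.7) with both marks, 10.8 (8.73 to 13.1) with H3K4me3 only and 0.343 (0.321 to 0.367) with neither. The ratio of H3Ac only to H3K4me3 only was 4.38 (3.45 to 5.60). It was 2.38 at a window threshold of 1e-04. Stat3 reads over the whole of each class differed less, at 2.38 RPKM with H3Ac only, 2.46 with both marks and 1.43 with H3K4me3 only.

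Stronger Stat3 regions overlapped H3Ac more often. When 1580 regions were divided into 4 classes of 395 by Stat3 density, H3Ac overlap was 24.6% (20.6 to 29.0) in the weakest class and 56.7% (51.8 to 61.5) in the strongest. H3K4me3 overlap was 24.6% (20.6 to 29.0) and 32.7% (28.2 to 37.4) in the same classes. The share with neither mark was 68.6% in the weakest and 38.7% in the strongest. Median Stat3 density was 26.5 in regions with H3Ac only, 20.8 with both marks, and 18.9 both with H3K4me3 only and with neither. Stat3 density 2 to 3 kb away was 1.38 RPKM with H3Ac only, 1.24 with both marks, 0.885 with H3K4me3 only and 0.862 with neither. Windows were called against the local mean, so the lowest density that could be called was on average higher near H3Ac. These differences in strength were not checked with another background.

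Averaged over the 1580 regions, both marks flanked Stat3 centres and were lower at the centre itself. H3Ac density at 200 to 500 bp from the centre was 3.48 times (3.42 to 3.54) that at 2 to 3 kb, and the density within 100 bp of the centre was 0.666 times (0.647 to 0.686) that at 200 to 500 bp. For H3K4me3 these ratios were 4.75 (4.66 to 4.83) and 0.912 (0.889 to 0.935). In regions with H3Ac only, the central H3Ac density was 0.513 times (0.480 to 0.548) that of the flanks. Among the 865 regions that overlapped neither mark, the flanks had 2.35 times (2.27 to 2.44) the H3Ac and 1.64 times (1.56 to 1.71) the H3K4me3 density at 2 to 3 kb, but some of these regions had a called mark region within 1 kb. In the 571 with none within 1 kb, the flank ratios were 1.79 (1.69 to 1.90) and 1.13 (1.04 to 1.23). Choosing regions without a called mark nearby limits density in the flanks but not at 2 to 3 kb, which tends to lower these ratios. Over the 865 regions, central density was 0.703 times (0.660 to 0.748) that of the flanks for H3Ac. For H3K4me3 it was 0.913 times (0.843 to 0.988). In the 571 regions with no called mark region within 1 kb the centre was not lower. Its density over that of the flanks was 1.16 (1.06 to 1.27) for H3Ac and 1.65 (1.45 to 1.86) for H3K4me3.

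**Figure D3:**
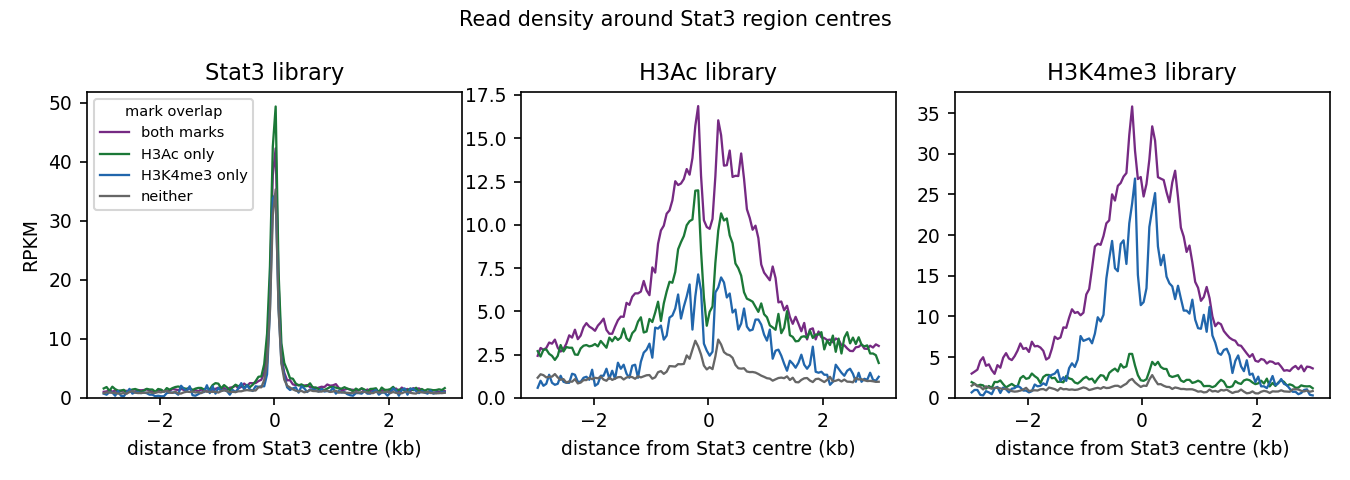
Read density (RPKM) within 3 kb of the centres of 1580 Stat3 regions, in bins of 50 bp, for the Stat3 (left), H3Ac (middle) and H3K4me3 (right) libraries; each line is the mean over regions overlapping both marks, H3Ac only, H3K4me3 only or neither. Mark density peaks on either side of the centre in each class shown, and over all regions the central H3Ac density is 0.666 times that at 200 to 500 bp. For regions overlapping neither mark it is 0.703 times.

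H3Ac and H3K4me3 regions largely coincided. Of the H3K4me3 regions, 71.7% (71.1 to 72.3) overlapped an H3Ac region, and 65.8% (65.2 to 66.4) of the H3Ac regions overlapped an H3K4me3 region. Regions that overlapped the other mark had median widths of 1400 bp for H3K4me3 and 1000 bp for H3Ac, and those that did not had a median width of 200 bp for each mark. Across 2 kb bins with any read, Spearman's rho was 0.309 for H3Ac and H3K4me3, 0.387 for Stat3 and H3Ac, and 0.209 for Stat3 and H3K4me3. Bins are not independent replicates. Of the reads used, 87.7% for Stat3, 62.1% for H3Ac and 12.9% for H3K4me3 lay more than 1 kb from every called region. Background reads therefore enter these values, and their part was not separated from shared marking. Among bins with at least 10 reads the Stat3 correlations were negative, at -0.114 with H3Ac and -0.0471 with H3K4me3. The filter acts on the summed reads of the libraries being correlated, which can by itself lower a correlation. H3Ac and H3K4me3 correlated at 0.428 in those bins. In 10 kb bins rho was 0.600 for H3Ac and H3K4me3, 0.755 for Stat3 and H3Ac, and 0.541 for Stat3 and H3K4me3.

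Stat3 reads had a shorter strand offset than reads of either mark. The offset was 119 ± 0.83 bp in the Stat3 library, 142 ± 0.16 bp in the H3Ac library and 144 ± 0.12 bp in the H3K4me3 library (jackknife error over 20 chromosomes). Stat3 reads within 500 bp of Stat3 regions had an offset of 106 ± 2.1 bp. More than 1 kb from every called region, the offset was 121 ± 1.3 bp for Stat3, 148 ± 0.44 bp for H3Ac and 123 ± 1.4 bp for H3K4me3, so away from regions only the H3Ac offset stood apart. These are vertices of fitted peaks; the most frequent distances in the whole libraries were 123 bp for Stat3, 144 bp for H3Ac and 151 bp for H3K4me3.

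**Figure D4:**
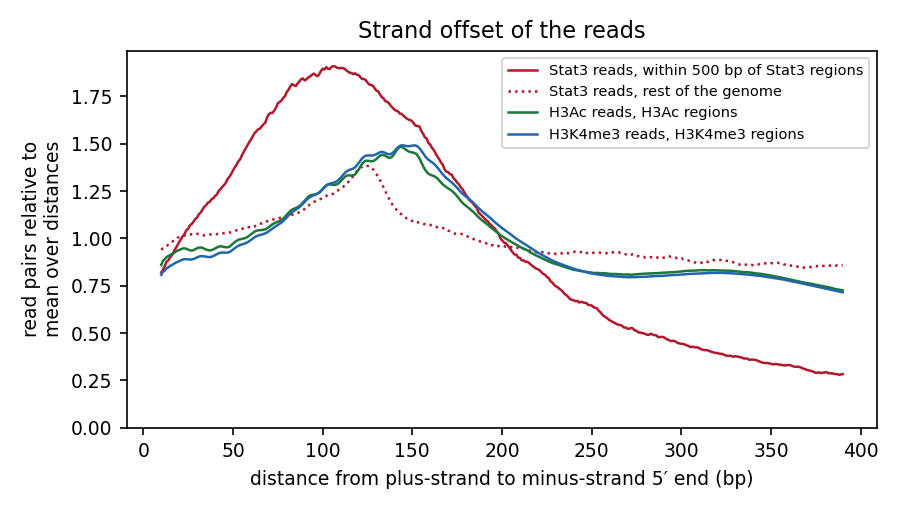
Pairs of plus-strand and minus-strand reads by the distance between their 5′ ends (bp), relative to the mean over the distances shown, for Stat3 reads near Stat3 regions (red, solid), Stat3 reads in the rest of the genome (red, dotted), H3Ac reads in H3Ac regions (green) and H3K4me3 reads in H3K4me3 regions (blue). The fitted offset is 106 bp for Stat3 reads near Stat3 regions, 140 bp for H3Ac and 142 bp for H3K4me3; pairs taken from short stretches thin out with distance.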

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

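Reads on the mitochondrial genome and the Y chromosome lay outside the chromosomes used for regions and exceeded the limit that a count of 0 allows, 3 reads. The Stat3 library held 699 mitochondrial and 2715 Y chromosome reads, the H3Ac library 226 and 879, and the H3K4me3 library 170 and 902. The share of all reads on the Y chromosome was 4.88 times (4.52 to 5.27) as high in the Stat3 library as in the H3Ac library and 4.84 times (4.49 to 5.22) as high as in the H3K4me3 library. Relative to distinct reads more than 1 kb outside all called regions, distinct Y chromosome reads came to 0.113% for Stat3, 0.0330% for H3Ac and 0.196% for H3K4me3, so the order of the libraries depended on the denominator. Mismatches were present in 48.1% of Stat3, 35.6% of H3Ac and 29.8% of H3K4me3 reads on the Y chromosome. No biological explanation was tested for these reads.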

How the results depend on the processing

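No paired analysis was possible because each antibody has 1 library and the shared replicate number only names it; leaving out a replicate was not possible either. The 1 kb margin, removal of mismatch-rich regions, the ratio per Mb, overlap with neither mark, overlap between marks and the correlations across bins were added after seeing the data. Results that need genes, promoters or sequence on mm9 were not run. Of the alternative counts, shares and ratios, 30 stayed within 1.5-fold (counts) or the counting interval (shares and ratios) and 31 moved outside. Of the alternative correlations, 3 stayed within 0.05, 4 moved further and 2 turned sign. Moving no reads and removing mismatch-rich regions left each Stat3 overlap within its interval. So did a larger minimum overlap, but that alternative could hardly change the result. Stat3 and mark regions share the same 200 bp windows, and 89.9% of Stat3 regions are a single window. Without mismatch-rich regions the ratio of Stat3 regions per Mb, H3Ac only to H3K4me3 only, was 4.90.

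The number of Stat3 regions was 4144 at a threshold of 1e-04, 771 at 1e-09 and 5421 with the genome-wide background; H3Ac regions numbered 15531 at 1e-09. Stat3 overlap with H3K4me3 was 26.7% at 1e-09, 27.2% thinned to equal reads, 28.2% with the genome-wide background and 44.0% within 1 kb. Overlap with H3Ac was 34.4% with all reads kept, 37.4% at 1e-04, 25.03% at 1e-09, 26.1% thinned, 34.4% with the genome-wide background and 60.3% within 1 kb. Overlap with neither was 58.8%, 57.2%, 64.5%, 63.7%, 61.2% and 35.9% in that order. H3K4me3 regions overlapped H3Ac in 70.6% with all reads kept, 73.5% at 1e-04, 63.6% at 1e-09, 62.5% thinned and 70.8% with reads not moved; the reverse was 72.2%, 53.8%, 82.98%, 79.3% and 67.4%. The ratio per Mb was 2.38 at 1e-04. Thinning and stricter thresholds shorten the H3Ac list by construction; the cause of the other moves was not tested. The Stat3 correlations turned to -0.114 with H3Ac and -0.0471 with H3K4me3 in bins of at least 10 reads, a filter on the summed reads of the libraries being correlated, and were 0.755 and 0.541 in 10 kb bins. Weak windows were partly missed in each library: of simulated windows with 5 added reads, 40% were recovered for Stat3, 48% for H3Ac and 32% for H3K4me3. Depth was not varied in the simulation. With 50 such windows per library, the differences between libraries were not tested.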

Other observations

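Of the tests reported here, the comparison of Stat3 with H3K4me3 offsets at their own regions both offset comparisons away from called regions, and the mark densities around regions with no mark within 1 kb were chosen after the results were seen, and so were the comparisons of clusters, wide regions and the X chromosome.

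Stat3 regions were clustered. Runs of at least 3 regions less than 50 kb apart occurred 43 times, against a mean of 1.5 under random placement and 4.1 on windows with a Stat3 read, where the highest of 100 placements was 11. The largest cluster lay on chromosome 2 at 128198001 to 128284000, with 6 Stat3 regions, of which 2 overlapped H3Ac and none overlapped H3K4me3. A cluster of 5 on chromosome 11 at 117739601 to 117830800 had 4 regions with H3Ac and 3 with H3K4me3. Chromosome 15 at 62656601 to 62668800 held 4 regions within 12.2 kb, of which 3 overlapped H3Ac and 0 H3K4me3.

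Wider mark regions more often held a Stat3 region, while Stat3 centres per Mb did not rise detectably with width. The share of H3Ac regions with a Stat3 region was 1.13% (0.980 to 1.30) up to 1 kb wide and 18.9% (11.6 to 29.3), 14 of 74, over 8 kb. For H3K4me3 regions these shares were 1.11% (0.938 to 1.32) and 14.3% (7.10 to 26.7). Per Mb of H3Ac regions there were 26.3 Stat3 centres (22.6 to 30.4) up to 1 kb and 19.3 (11.4 to 30.4) over 8 kb, with 27.7 to 32.3 in the classes between, differences not resolved at this depth. Per Mb of H3K4me3 regions there were 22.1 (18.3 to 26.4) up to 1 kb, 16.8 (14.4 to 19.6) over 1 to 2 kb, 14.2 (11.7 to 17.0) over 2 to 4 kb, 18.4 (13.4 to 24.8) over 4 to 8 kb and 20.7 (10.3 to 37.1) over 8 kb, so the class of 2 to 4 kb lay below the narrowest. The widest H3Ac region, on chromosome 14 at 54788801 to 54849000, held 5550 H3Ac reads and 0 Stat3 regions, and the widest H3K4me3 region lay inside it at 54799001 to 54839400. Chromosome 11 at 87555601 to 87574600, an H3Ac region of 19 kb, held 2 Stat3 regions.

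The X chromosome carried fewer regions per Mb than the autosomes in each library, at 0.192 times (0.118 to 0.294) for Stat3, 0.291 for H3Ac and 0.396 for H3K4me3. With autosomal reads thinned to the read density of X, the ratios were 1.197 (0.747 to 1.83) for Stat3, 0.828 (0.758 to 0.904) for H3Ac and 0.581 (0.534 to 0.630) for H3K4me3. The Stat3 difference was thus not detectable at equal read density.

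Stat3 regions outside both marks could be chance pile-ups, reads from collapsed repeats, or places whose marks fell below the threshold. In a random part of the Stat3 reads, 320 such regions were called, and in the reads left out these were 22.1 times (21.01 to 23.3) as dense as the surrounding 10 kb, which argues against chance pile-ups for them; of the 893 regions outside both marks only 302 overlapped a region called in that part, and the others were not tested. The mismatch share over all 893 was 1.1 times (1.05 to 1.15) that of the library. For the set as a whole this argues against collapsed repeats whose copies differ from the reference, although 13 of the regions were mismatch-rich. Copies that match the reference would not raise this share, so they were not tested. Density within 1 kb over that 5 to 10 kb away was 1.88 for H3Ac and 1.42 for H3K4me3, but called mark regions lie within that 1 kb for some regions; for the 592 with none it was 1.47 (1.42 to 1.51) and 1.03 (0.982 to 1.07), and 1.90 (1.84 to 1.97) and 3.52 (3.33 to 3.71) once called regions of the mark were left out of the flank. The H3K4me3 values fell on opposite sides of the bounds of 1.2 and 2 with the choice of flank. The first flank could hold called regions while the 592 regions had none within 1 kb, which tends to lower its ratio. Against the flank without called regions, reads of both marks were denser near these Stat3 regions. Only H3K4me3 passed the bound of 2, and both flanks were chosen after the results were seen. Whether these reads are marks below the threshold or recovery of open chromatin stays open, because no input library was used. Stat3 regions in marks were not part of the repeat test. Their mismatch shares were 27.2% with both marks, 26.1% with H3K4me3 only and 13.9% with H3Ac only, against 14.6% in the library. Mismatch-rich regions numbered 22 with both marks, 10 with H3K4me3 only and 2 with H3Ac only.

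The shorter Stat3 strand offset may reflect shorter inserts throughout that library or fragments shorter than a nucleosome at bound places, and 4 different offset comparisons were made without settling it. In marked regions without a Stat3 region the Stat3 offset was 95.8 bp, a difference of -10.1 bp (-16.3 to -4.0) from Stat3 regions. An offset within 2 errors was predicted for short inserts throughout and a longer one otherwise, and neither was met. Reads at Stat3 regions were taken with 500 bp on either side, those in marked regions with no margin. Single windows of 200 bp made up 39.1% of H3Ac and 22.6% of H3K4me3 regions, and pairs there thin out with distance. H3K4me3 reads in the same marked regions had an offset of 142 ± 1.5 bp, so the missing margin did not by itself give a short offset. Within 500 bp of Stat3 regions the offset was 143 ± 2.4 bp for H3K4me3 and 138 ± 1.3 bp for H3Ac. No prediction was made for these offsets, and the effect of the margin on Stat3 reads was not measured. The difference of -10.1 bp met neither prediction and cannot decide between them. At their own regions H3K4me3 offsets exceeded Stat3 offsets by 35.6 bp (30.4 to 40.8), but this restates the pattern, and whether Stat3 binds weakly in the marked regions without a Stat3 region is unsettled. Away from called regions the comparison depended on the library chosen. H3Ac exceeded Stat3 by 26.7 bp (23.9 to 29.5), as shorter Stat3 inserts predicted. H3K4me3 exceeded Stat3 by 2.08 bp (-1.77 to 5.93), which did not meet that prediction. The H3K4me3 offset itself was 142 bp in its own regions and 123 bp away from called regions. The offset thus varied within 1 library, and the comparison cannot decide about insert length. Antibody and library cannot be told apart with 1 library each.

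Marked regions without a Stat3 region were also enriched in Stat3 reads, 5.93-fold (5.89 to 5.96) for H3Ac and 5.29-fold (5.26 to 5.32) for H3K4me3 over the rest of the genome. Weak Stat3 binding below the threshold is a candidate explanation, which predicted an offset equal to that at Stat3 regions. The measured difference of -10.1 bp met neither that prediction nor its opposite, a longer offset. Weak binding and recovery of open chromatin cannot be told apart here without an input library.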
